A study of Raphidocelis subcapitata with 72 samples.

How the data were processed

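RNA-seq libraries were made with a strand-specific poly(A) kit and sequenced in paired-end mode, per the labels' protocols. The labels place them in 6 groups, which are particle-free, nFe3O4 and nZVI cultures at 1 h and 4 h, each with 3 biological replicates and 4 sub-samples per replicate (a to d, L1 to L4). These are read here as sequencing lanes of one library, as all 4 carry one replicate number, though the labels do not use the word lane. Headings of a transformed table deposited by the authors give the 4 of a replicate a shared sample number, which fits that reading. The labels do not say whether replicates were grown from separate inocula, so p-values measure the spread between these libraries. Bcl2fastq, Trimmomatic, HISAT2, SAMtools, bedtools 2.27.1, DESeq2 and DESeq are named in the submitters' processing notes, without roles or order. The genome build, the annotation and the counting options are not given in the sources used here.

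The authors deposited a table of whole read counts per gene with 72 lane columns, per the file headers, which is not normalized. Its low values were mostly even: 63.4% of lane counts from 1 to 20 were, as when both mates of a pair are counted, so a count is closer to a read than to a fragment. The authors also deposited a table of 50 genes on the log2 scale, named as regularized log values and centred on each gene's mean. There are 7 deposited tables of the authors' own comparisons, which per the file headers hold DESeq2 output: a mean normalized count, a log2 fold change with its standard error (other values of the table), a Wald statistic given as a score, and a p-value with its adjusted value. Only genes under an adjusted p-value of 0.05 are in those deposited tables. The mean normalized count, among the other values of the authors' deposited tables, had a median ratio of 0.475 to the mean lane count over 10517 genes, so the counts behind those tables are not the values of the count table. The authors' deposited tables hold 10824 genes, of which 10537 are in the count table and 285 have locus numbers below 360, the lowest in the count table; these were not analysed here. Values from the authors' deposited tables are printed as theirs and were not used in any test of differences.

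Lane counts were summed to libraries. The 4 lane columns of nFe3O4 1 h replicate 2 were exact copies of 1 lane column of nFe3O4 1 h replicate 1 and were left out, which leaves 68 lane columns, 17 libraries and 2 libraries in that group. In the other libraries the lanes differed little, with a chi-square per degree of freedom of 2.40 to 3.57 over genes with at least 20 counts, against 17.2 to 50.2 between libraries of a group. Library totals ran from 26322767 to 43364641 counts over 12181 genes, and the common coefficient of variation between libraries of a group was 0.190.

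Differences were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by the quasi-likelihood test on library counts, with TMM scaling and one model of 6 group means over all 17 libraries. The low-count filter by group removed 340 of 12181 genes and left 11841. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05. The comparisons were each particle against the control and the particles against each other at each hour, 4 h against 1 h within each condition and over the mean of the 3 conditions, and the difference of each particle's effect between the hours. Group values are CPM on TMM-scaled library sizes, as mean ± SD over libraries. Log2 fold changes are edgeR's estimates with a standard error taken from the test statistic. The overlap of the particle responses was set beside 20 simulations of unchanged groups against the same control libraries and beside the product of list sizes over genes tested. Names in the count table were compared with those in the authors' transformed table by Pearson's r over 49 genes, on log2(CPM + 0.5) centred per gene.

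The files do not pair the locus identifiers with gene names or products, and no annotation was used here, so gene groups were not tested. The rule for named genes, set before the data were examined, then takes the 2 genes with the largest rise and the 2 with the largest fall per comparison, among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups' libraries. For comparisons with fewer such genes, those present are named.

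The fit was tested on simulated counts drawn from the libraries' means and sizes over 11841 genes, with known fold changes in 67, 67 and 66 genes. For nFe3O4 against control at 1 h it recovered 22.4% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 92.4% of those changed 4-fold, and 2.36% of its calls were false. For nZVI against control at 1 h the shares were 26.9%, 70.1% and 92.4%, with 5.26% false, and at 4 h 23.9%, 73.1% and 97%, with 5.84% false. The simulations changed far fewer genes than were called in the data, with rises and falls balanced. Each gene was drawn on its own, without differences between libraries of a group that many genes share. These shares may therefore not carry over to the data.

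Alternatives were DESeq2 1.42.0, other size factors, no filter and a stricter filter of 1 CPM in 3 libraries, fits on the compared groups alone, replicate blocks, each library left out in turn, a fold change of at least 2, lane 1 alone and lane columns as samples. Another 3 were added after seeing the data: the names control and nZVI exchanged, the copied columns kept as a library, and a covariate for the axis along which libraries of a group differ.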

Results

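Messenger RNA of the unicellular green alga Raphidocelis subcapitata, a freshwater species widely used in toxicity tests, was sequenced after exposure to iron nanoparticles. Cultures received 100 mg/L of nanoscale zero-valent iron (nZVI), 100 mg/L of magnetite nanoparticles (nFe3O4), or no particles, and were sampled after 1 h and 4 h. The labels name 3 biological replicates in each of the 6 groups and 4 sub-samples of each, marked a to d and L1 to L4. These were read as sequencing lanes of one library and summed, and every n below rests on that reading. The labels do not use the word lane, but headings of the authors' transformed table give the 4 of a replicate a shared sample number. Entered as separate samples, they gave between 1519 and 7280 changed genes in the 12 comparisons. The 4 columns of nFe3O4 1 h replicate 2 held exactly the values of 1 lane column of nFe3O4 1 h replicate 1, so this library was counted as 1 sample with replicate 1 and left out. The 17 distinct libraries held between 26322767 and 43364641 counts over 12181 genes, of which 11841 were tested. The 10 most abundant genes of a library took between 20.2% and 26.4% of its counts.

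The names control and nZVI did not stand for the same libraries in all deposited tables. Over 49 genes of the authors' transformed table, each of the 12 libraries headed control or nZVI in the count table correlated best with a library of the other name, the same hour and the same replicate number, with r across genes between 0.963 and 0.991. Against the library of their own name, r lay between -0.791 and 0.441. The 5 distinct nFe3O4 libraries matched their own names, with r between 0.972 and 0.988. Genes are not independent replicates, so these r values describe the match only. The groups are therefore called labelled control and labelled nZVI, after the headings of the count table, and every direction between them depends on those headings. In the authors' deposited table of nZVI against control, log2 fold changes ran the opposite way, with r across genes of -0.976 at 1 h and -0.986 at 4 h.

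**Figure D1:**
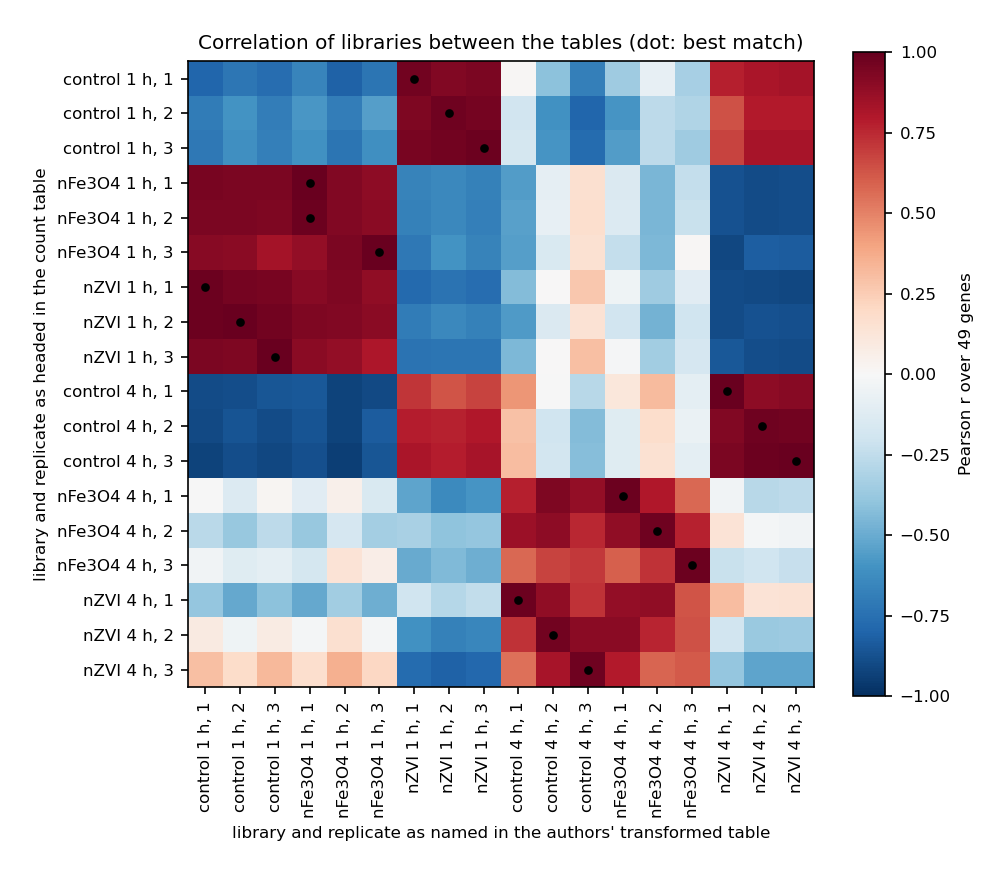
Pearson r over 49 genes between each library as headed in the count table (vertical axis) and each library as named in the authors' transformed table (horizontal axis), with a dot at each library's best match. The dots of all 12 libraries headed control or nZVI lie on the other name, with r of 0.963 to 0.991, and the copied nFe3O4 1 h replicate 2 falls on replicate 1.

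The first comparison asked how algae exposed to nFe3O4 for 1 h differed from particle-free algae of the same hour. RSUB_08785 stood at 156 CPM ± 31.0 (SD, n = 2) with nFe3O4 and at 10.7 CPM ± 1.75 (SD, n = 3) in the labelled control. RSUB_09261 stood at 24.5 CPM ± 0.536 (SD, n = 2) against 1.60 CPM ± 0.406 (SD, n = 3). Here and in each other comparison of 2 groups, all libraries of one group lay above all of the other for each gene named by the rule. The rule requires this, so it is no separate evidence of a difference. In the opposite direction, RSUB_07490 stood at 25.2 CPM ± 16.3 (SD, n = 2) with nFe3O4 against 299 CPM ± 101 (SD, n = 3). RSUB_08235 stood at 56.5 CPM ± 36.3 (SD, n = 2) against 643 CPM ± 225 (SD, n = 3). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, RSUB_08785 differed by a log2 fold change of 3.87 (SE 0.25, adjusted p = 2.62e-07) and RSUB_09261 by 3.93 (SE 0.34, adjusted p = 1.67e-06). RSUB_07490 was lower by the same test, at -3.57 (SE 0.49, adjusted p = 6.95e-05), as was RSUB_08235, at -3.51 (SE 0.48, adjusted p = 6.99e-05). In all, 3424 of the 11841 genes changed, 1813 higher and 1611 lower with nFe3O4 than in the labelled control (1691 and 1719 with RLE in place of TMM size factors), and 1166 of them changed at least 2-fold. Without nFe3O4 1 h replicate 3 the count was 2123, and with lane 1 alone 2202. In the authors' deposited table of this comparison, RSUB_08785 had a log2 fold change of -0.42, and RSUB_09261, RSUB_07490 and RSUB_08235 were not listed. Fold changes in that deposited table correlated across genes at -0.041 with this comparison here and at -0.966 with labelled nZVI against nFe3O4. It therefore does not hold the same contrast as here.

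The second comparison asked the same of nZVI at 1 h. RSUB_08785 stood at 212 CPM ± 30.0 (SD, n = 3) in the labelled nZVI libraries against 10.7 CPM ± 1.75 (SD, n = 3) in the labelled control. RSUB_07060 stood at 45.5 CPM ± 13.1 (SD, n = 3) against 2.33 CPM ± 0.386 (SD, n = 3). RSUB_11916 stood at 2.38 CPM ± 1.63 (SD, n = 3) in labelled nZVI against 32.6 CPM ± 3.90 (SD, n = 3), and RSUB_08235 at 72.9 CPM ± 44.5 (SD, n = 3) against 643 CPM ± 225 (SD, n = 3). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold changes were 4.32 for RSUB_08785 (SE 0.24, adjusted p = 1.42e-08) and 4.28 for RSUB_07060 (SE 0.34, adjusted p = 2.51e-07). They were -3.79 for RSUB_11916 (SE 0.38, adjusted p = 1.40e-06) and -3.14 for RSUB_08235 (SE 0.40, adjusted p = 1.54e-05), from the same test. Of the 11841 genes, 4892 changed, 2505 higher and 2387 lower in labelled nZVI (2364 and 2509 with RLE), and 1804 changed at least 2-fold. The authors' deposited table gave the opposite direction for each of these 4 genes, with log2 fold changes of -4.39 for RSUB_08785, -4.35 for RSUB_07060, 3.77 for RSUB_11916 and 3.18 for RSUB_08235.

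**Figure D2:**
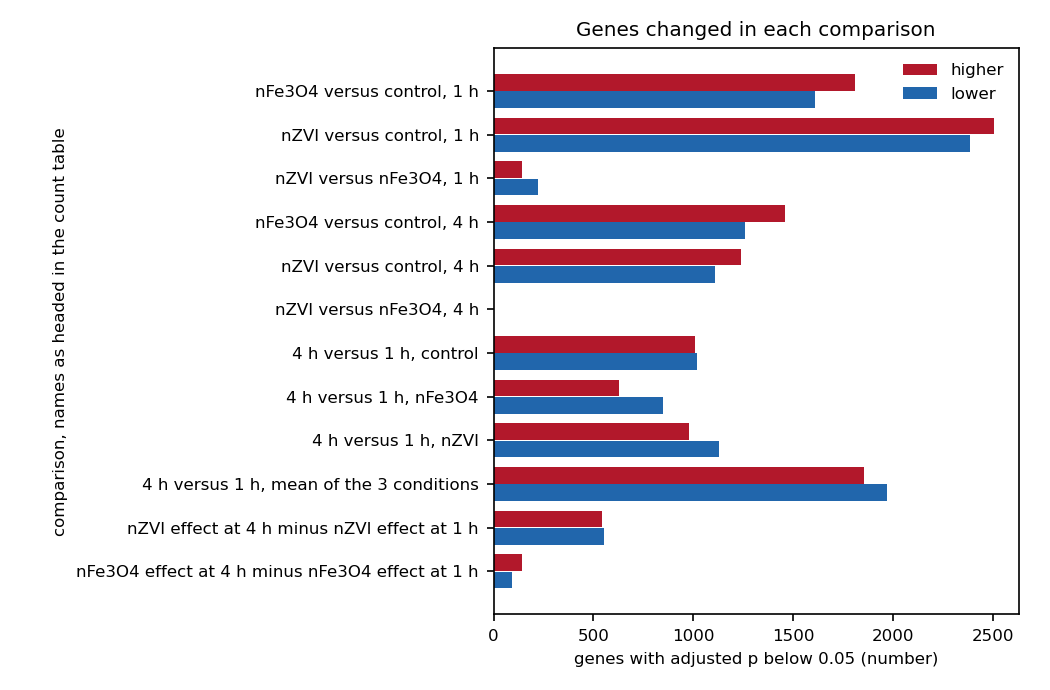
Number of genes with an edgeR adjusted p below 0.05 in each comparison (horizontal axis), split into higher and lower, with names as headed in the count table (vertical axis). The bars against the labelled control hold between 1112 and 2505 genes per direction, and those between labelled nZVI and nFe3O4 hold 143 and 222 genes at 1 h and 0 and 1 gene at 4 h.

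At both hours the labelled control stood apart from the other 2 groups. At 1 h, 1263 genes were higher in the labelled control than in both nFe3O4 and labelled nZVI and 1538 were lower, whereas 116 genes set nFe3O4 apart from both other groups and 232 set labelled nZVI apart. At 4 h, 815 genes were higher and 974 lower in the labelled control than in both others. By edgeR's test 1 gene set labelled nZVI apart and 0 genes set nFe3O4 apart. Between labelled nZVI and nFe3O4, 835 of 11841 genes had an unadjusted p below 0.05 in that test, and DESeq2 called 26. A share of 0.05 of unchanged genes would fall below that p by chance, and 835 of 11841 is a larger share. The log2 fold changes of nFe3O4 and of labelled nZVI against the labelled control correlated across genes with r = 0.868 at 1 h and 0.843 at 4 h. Unchanged groups simulated against the same control libraries, with genes drawn independently, gave a mean r of 0.459 at 1 h and 0.502 at 4 h over 20 simulations. They gave 0 shared calls, but groups without change have almost no calls to share. That value therefore does not tell how many shared calls come from the controls. The covariance of the fold changes was 0.636 at 1 h against 0.0480 in the simulation, a difference of 0.588, and 0.277 at 4 h against 0.0461, a difference of 0.231. Independent lists of these sizes would share 384 higher and 325 lower genes at 1 h, where 1538 and 1263 were shared, and 153 higher and 118 lower genes at 4 h, where 974 and 815 were shared. Genes changed in opposite directions numbered 3 at 1 h and 0 at 4 h. The 3 control libraries of an hour were not split between the comparisons, so part of the excess may come from the shared controls. Under the names of the authors' deposited tables, the group that stood apart in more genes is nZVI, and nFe3O4 against control is the comparison with 365 genes at 1 h and 1 at 4 h here. The authors' deposited tables listed 4601 and 1587 genes for it.

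The libraries labelled nZVI were compared with nFe3O4 at 1 h to ask how the particle types differed at the same dose. RSUB_12574 stood at 11.8 CPM ± 0.735 (SD, n = 3) in labelled nZVI, at 36.5 CPM ± 2.72 (SD, n = 2) with nFe3O4 and at 54.9 CPM ± 6.13 (SD, n = 3) in the labelled control. RSUB_08164 stood at 4.91 CPM ± 1.61 (SD, n = 3) in labelled nZVI and at 16.1 CPM ± 2.80 (SD, n = 2) with nFe3O4. RSUB_02091 was at 138 CPM ± 19.5 (SD, n = 3) against 31.3 CPM ± 1.29 (SD, n = 2), and RSUB_01781 at 25.7 CPM ± 4.19 (SD, n = 3) against 7.50 CPM ± 3.73 (SD, n = 2). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold changes were -1.63 for RSUB_12574 (SE 0.12, adjusted p = 3.42e-06) and -1.71 for RSUB_08164 (SE 0.30, adjusted p = 0.00885). The same test gave 2.14 for RSUB_02091 (SE 0.43, adjusted p = 0.0169) and 1.78 for RSUB_01781 (SE 0.32, adjusted p = 0.0112). In all 365 genes changed, 143 higher and 222 lower in labelled nZVI, and 56 changed at least 2-fold; DESeq2 called 663 genes. Lane 1 alone gave 87, and a covariate for the axis along which libraries of a group differed, added after seeing the data, gave 1675, with the larger number turned to higher (956 higher, 719 lower). The count fell to 12 without nFe3O4 1 h replicate 3, 158 without nFe3O4 1 h replicate 1, 185 without nZVI 1 h replicate 2 and 131 without nZVI 1 h replicate 3, and a fit on these 2 groups alone called 2 genes. In edgeR's fit without nFe3O4 1 h replicate 3, adjusted p rose to 0.185 for RSUB_02091 (log2 fold change 2.18), 0.183 for RSUB_01781 (1.34) and 0.137 for RSUB_08164 (-1.52), and that of RSUB_02091 to 0.0809 (2.10) without nFe3O4 1 h replicate 1. On these 2 groups alone it was 0.21 for RSUB_01781 (1.77) and 0.201 for RSUB_08164 (-1.73), in edgeR's fit. In the authors' deposited table of nZVI against nFe3O4 at 1 h, the log2 fold changes were 0.76 for RSUB_12574, 1.54 for RSUB_08164, 1.61 for RSUB_02091 and 2.41 for RSUB_01781. Fold changes in that deposited table correlated across genes at -0.0774 with this comparison here and at -0.973 with nFe3O4 against the labelled control. It therefore does not hold the same contrast as here, and like or unlike signs for these genes are not read.

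At 4 h the comparisons with the labelled control were repeated on cultures exposed for longer. RSUB_07060 stood at 3.22 CPM ± 1.20 (SD, n = 3) in the labelled control, at 32.0 CPM ± 3.89 (SD, n = 3) with nFe3O4 and at 35.0 CPM ± 14.8 (SD, n = 3) in labelled nZVI. RSUB_02480 ran the other way, from 156 CPM ± 52.1 (SD, n = 3) in the labelled control to 40.1 CPM ± 4.58 (SD, n = 3) with nFe3O4 and 45.6 CPM ± 10.9 (SD, n = 3) in labelled nZVI. RSUB_09261 rose from 3.28 CPM ± 1.13 (SD, n = 3) in the labelled control to 28.6 CPM ± 6.11 (SD, n = 3) with nFe3O4, and RSUB_04006 fell from 31.1 CPM ± 3.95 (SD, n = 3) to 8.53 CPM ± 1.76 (SD, n = 3). RSUB_12703 rose from 5.54 CPM ± 0.0907 (SD, n = 3) in the labelled control to 52.9 CPM ± 21.0 (SD, n = 3) in labelled nZVI. For nFe3O4, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave log2 fold changes of 3.30 for RSUB_07060 (SE 0.32, adjusted p = 1.97e-05) and 3.11 for RSUB_09261 (SE 0.31, adjusted p = 1.97e-05). It gave -1.95 for RSUB_02480 (SE 0.27, adjusted p = 2.10e-04) and -1.86 for RSUB_04006 (SE 0.31, adjusted p = 7.18e-04). For labelled nZVI the same test gave 3.42 for RSUB_07060 (SE 0.32, adjusted p = 1.41e-05) and 3.25 for RSUB_12703 (SE 0.33, adjusted p = 1.95e-05). RSUB_12574 was lower in labelled nZVI by -1.96 (SE 0.11, adjusted p = 4.11e-08), and RSUB_02480 by -1.77 (SE 0.27, adjusted p = 4.46e-04), from that test.

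With nFe3O4 at 4 h, 2720 genes changed against the labelled control, 1459 higher and 1261 lower (1284 and 1433 with RLE), and 512 changed at least 2-fold. In labelled nZVI at 4 h, 2353 genes changed against the labelled control, 1241 higher and 1112 lower (1147 and 1221 with RLE), and 485 changed at least 2-fold. The nFe3O4 count was 1704 without nFe3O4 4 h replicate 1, 1806 without nFe3O4 4 h replicate 3 and 1754 without control 4 h replicate 3. The labelled nZVI count was 1369 without nZVI 4 h replicate 3, and 3670 with the covariate added after seeing the data. Lane 1 alone gave 1466 for nFe3O4 and 1226 for labelled nZVI. Against the labelled control at both hours, the direction with more genes turned between the scalings, so none is read as the prevailing one. In the authors' deposited table of nZVI against control at 4 h, the log2 fold changes were -3.41 for RSUB_07060, -3.25 for RSUB_12703, 1.99 for RSUB_12574 and 1.81 for RSUB_02480, opposite in sign to those from the count table. The authors' deposited table of nFe3O4 against control at 4 h gave RSUB_04006 a log2 fold change of -0.43 and did not list RSUB_07060, RSUB_09261 or RSUB_02480. Its fold changes correlated across genes at 0.34 with the same comparison here and at -0.992 with labelled nZVI against nFe3O4. It therefore does not hold the same contrast as here.

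**Figure D3:**
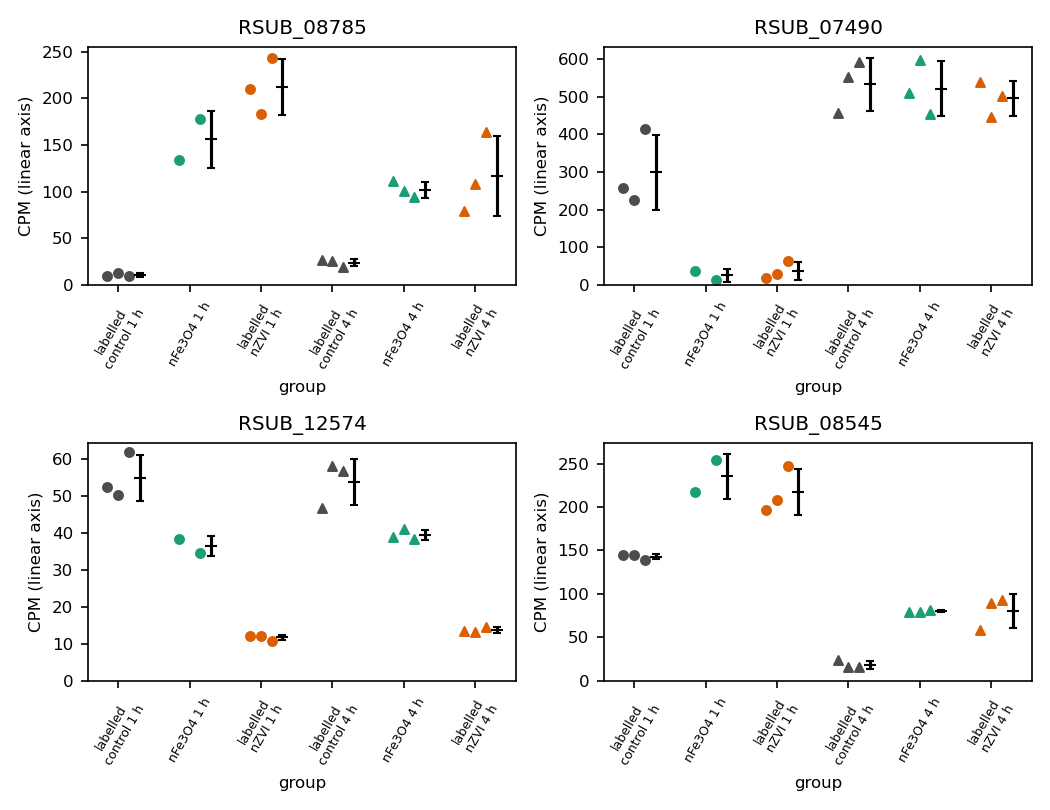
CPM on linear axes for RSUB_08785, RSUB_07490, RSUB_12574 and RSUB_08545 in each library (points; circles 1 h, triangles 4 h), with the mean ± SD of each group beside them (2 libraries for nFe3O4 1 h, 3 for each other group). RSUB_12574 lies at 10.9 to 12.3 CPM at 1 h and 13.2 to 14.6 CPM at 4 h in labelled nZVI, below every nFe3O4 and labelled control library, whose lowest value is 34.6 CPM.

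Between labelled nZVI and nFe3O4 at 4 h, the number of genes called depended on the fit, and edgeR's planned fit called 1. RSUB_12574 stood at 13.8 CPM ± 0.730 (SD, n = 3) in labelled nZVI, at 39.4 CPM ± 1.43 (SD, n = 3) with nFe3O4 and at 53.9 CPM ± 6.22 (SD, n = 3) in the labelled control. Its log2 fold change between labelled nZVI and nFe3O4 was -1.51 (SE 0.11, adjusted p = 3.20e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Thus 1 gene was lower and 0 genes were higher by edgeR, while DESeq2 called 26 genes. In edgeR's test 835 of 11841 genes had an unadjusted p below 0.05. This is a larger share than the 0.05 of unchanged genes that would fall below it by chance. The edgeR count was 4 without nZVI 4 h replicate 3. It was 341, 280 higher and 61 lower, with a covariate for the axis along which libraries of a group differed, added after seeing the data. The authors' deposited table of nZVI against nFe3O4 at 4 h gave RSUB_12574 a log2 fold change of 0.49. Its fold changes correlated across genes at 0.356 with this comparison here and at -0.984 with nFe3O4 against the labelled control. It therefore does not hold the same contrast as here. That deposited table listed 5815 genes, and the authors' deposited table of nFe3O4 against control at 4 h listed 1587.

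The difference of effects between the hours was tested to ask whether the response at 4 h was that of 1 h. RSUB_07490, at 25.2 CPM ± 16.3 (SD, n = 2) with nFe3O4 and 37.3 CPM ± 24.0 (SD, n = 3) in labelled nZVI at 1 h, stood at 4 h at 521 CPM ± 73.0 (SD, n = 3) and 496 CPM ± 46.2 (SD, n = 3), beside 533 CPM ± 69.9 (SD, n = 3) in the labelled control. RSUB_11916 went from 2.38 CPM ± 1.63 (SD, n = 3) to 27.5 CPM ± 1.86 (SD, n = 3) in labelled nZVI, and from 32.6 CPM ± 3.90 (SD, n = 3) to 44.4 CPM ± 1.56 (SD, n = 3) in the labelled control. RSUB_09199 went from 77.3 CPM ± 13.1 (SD, n = 3) to 38.5 CPM ± 18.2 (SD, n = 3) in labelled nZVI, and from 6.23 CPM ± 0.700 (SD, n = 3) to 15.6 CPM ± 2.38 (SD, n = 3) in the labelled control. The effect of labelled nZVI at 4 h minus that at 1 h was 2.90 on the log2 scale for RSUB_07490 (SE 0.54, adjusted p = 0.0044) and 3.10 for RSUB_11916 (SE 0.48, adjusted p = 0.0018) by edgeR's test with Benjamini-Hochberg adjustment. It was -2.33 for RSUB_09199 (SE 0.34, adjusted p = 0.00143) and -2.23 for RSUB_12662 (SE 0.36, adjusted p = 0.00221). For nFe3O4 the difference was 3.54 for RSUB_07490 (SE 0.59, adjusted p = 0.00823), 3.01 for RSUB_11916 (SE 0.52, adjusted p = 0.00966), -1.87 for RSUB_11161 (SE 0.38, adjusted p = 0.0194) and -1.81 for RSUB_11583 (SE 0.30, adjusted p = 0.00823), by the same test.

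The effect of labelled nZVI differed between the hours in 1098 genes, 543 with a higher and 555 with a lower value at 4 h. Of these, 88.9% had the larger effect at 1 h, where the median absolute log2 fold change was 1.04 against 0.31 at 4 h, and 371 had opposite signs at the 2 hours. The effect of nFe3O4 differed in 233 genes, 141 higher and 92 lower, of which 91% had the larger effect at 1 h. With the names control and nZVI exchanged it differed in 46 genes, 11 higher and 35 lower. The share with the larger effect at 1 h was not taken for those names. The 1098 and the 233 genes were picked by the difference of the same 2 effects whose sizes are compared. The shares and medians therefore describe the picked genes, and the sizes may be overstated. Against the labelled control, 951 genes were higher with nFe3O4 at both hours and 790 lower, where independent lists would share 223 and 172, and 19 genes changed in opposite directions. For labelled nZVI, 950 genes were higher and 754 lower at both hours, where independent lists would share 263 and 224, and 20 changed in opposite directions. Per the protocol, flasks were sampled at both hours, so the hours may share cultures and part of this agreement may come from them. The 1098 fell to 633 without control 1 h replicate 3, 532 without control 4 h replicate 1, 652 without nZVI 4 h replicate 1 and 638 without nZVI 4 h replicate 2. The 233 fell to 18 without nFe3O4 1 h replicate 3, 143 without control 1 h replicate 1, 100 without control 1 h replicate 3, 125 without nFe3O4 4 h replicate 3 and 78 without control 4 h replicate 1; DESeq2 called 460. Lane 1 alone gave 387 and 114, and a covariate for the axis along which libraries of a group differed, added after seeing the data, gave 2035 and 641.
In edgeR's fit without nFe3O4 1 h replicate 3 the 4 nFe3O4 genes no longer passed, with adjusted p of 0.078 for RSUB_07490 (difference 2.99), 0.0811 for RSUB_11916 (2.46), 0.118 for RSUB_11161 (-1.68) and 0.0774 for RSUB_11583 (-1.65). RSUB_11161 also failed without control 1 h replicate 1, control 1 h replicate 3 or control 4 h replicate 1, with adjusted p of 0.0519, 0.058 and 0.0566 and differences of -1.69, -1.87 and -1.87. With lane 1 alone, the difference was -1.82 for RSUB_12662 with labelled nZVI and -1.45 for RSUB_11161 with nFe3O4, and neither passed (adjusted p of 0.0644 and 0.142, edgeR).

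Time in culture was compared within each condition. The protocol says flasks were sampled at both hours, so libraries of the hours may not be independent, and the main fit has no block for this. RSUB_08545 fell between 1 h and 4 h in all 3 conditions, from 143 CPM ± 3.07 (SD, n = 3) to 18.6 CPM ± 4.46 (SD, n = 3) in the labelled control, from 235 CPM ± 26.1 (SD, n = 2) to 80.3 CPM ± 1.45 (SD, n = 3) with nFe3O4 and from 217 CPM ± 26.8 (SD, n = 3) to 80.3 CPM ± 19.3 (SD, n = 3) in labelled nZVI. RSUB_04889 fell from 13.7 CPM ± 2.54 (SD, n = 3) to 1.5 CPM ± 0.664 (SD, n = 3) in the labelled control. RSUB_05053 fell from 20.9 CPM ± 2.01 (SD, n = 2) to 5.66 CPM ± 0.899 (SD, n = 3) with nFe3O4. In labelled nZVI, RSUB_06945 fell from 31.7 CPM ± 8.13 (SD, n = 3) to 7.53 CPM ± 1.08 (SD, n = 3) and RSUB_07058 from 49.6 CPM ± 12.9 (SD, n = 3) to 12.3 CPM ± 2.36 (SD, n = 3). RSUB_01551 and RSUB_01552, neighbouring locus numbers, had the largest rises over the mean of the conditions among genes named by the rule, with near-equal log2 changes. The mean CPM of RSUB_01551 was the higher in every group, at 356.9 against 267.5 in labelled nZVI at 4 h. Whether their reads can be told apart is uncertain. RSUB_01551 stood at 437 CPM ± 417 (SD, n = 3) with nFe3O4 at 4 h, where its libraries ran from 103 to 904 CPM, and at 18 CPM ± 17.7 (SD, n = 2) at 1 h.

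Over the mean of the 3 conditions, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave 4 h minus 1 h log2 changes of 3.83 for RSUB_01551 (SE 0.57, adjusted p = 9.54e-05) and 3.82 for RSUB_01552 (SE 0.56, adjusted p = 9.34e-05). It gave -2.10 for RSUB_04889 (SE 0.19, adjusted p = 8.72e-07) and -1.98 for RSUB_08545 (SE 0.10, adjusted p = 8.49e-09). In the authors' deposited table of 4 h against 1 h these were 3.81, 3.83, -2.03 and -1.83, and r across the listed genes was 0.975. Within the labelled control, the change was -3.16 for RSUB_04889 (SE 0.35, adjusted p = 7.11e-05) and -2.94 for RSUB_08545 (SE 0.18, adjusted p = 4.15e-07) in edgeR's test. Within nFe3O4 it was -1.95 for RSUB_04889 (SE 0.34, adjusted p = 0.00126) and -1.89 for RSUB_05053 (SE 0.25, adjusted p = 1.63e-04), and within labelled nZVI it was -2.07 for RSUB_06945 (SE 0.20, adjusted p = 5.05e-06) and -2.0 for RSUB_07058 (SE 0.30, adjusted p = 2.63e-04), in edgeR's test. RSUB_07490 and RSUB_11916 rose in labelled nZVI by 3.74 (SE 0.42, adjusted p = 1.95e-05) and 3.54 (SE 0.37, adjusted p = 1.16e-05), from the same fit. RSUB_01551 and RSUB_01552 rose in the labelled control by 3.42 (adjusted p = 0.0171) and 3.39 (adjusted p = 0.0181), and with nFe3O4 by 4.61 (adjusted p = 0.0115) and 4.6 (adjusted p = 0.0113), in edgeR's test.
These 4 rises did not pass in edgeR's fit without certain single libraries, though each kept its sign. In the labelled control, with log2 changes between 2.60 and 3.08, adjusted p was 0.0699 and 0.0729 without control 1 h replicate 2, 0.0737 and 0.0748 without control 1 h replicate 3, and 0.0895 and 0.0938 without control 4 h replicate 1. With nFe3O4 it was 0.123 and 0.124 without nFe3O4 1 h replicate 3 alone (3.84 and 3.86), and 0.0953 and 0.0888 in edgeR's fit on the 2 groups (4.6 and 4.59).

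Between 1 h and 4 h, 2028 genes changed in the labelled control (1009 higher, 1019 lower at 4 h; 1042 and 919 with RLE), 1482 with nFe3O4 (631 higher, 851 lower) and 2110 in labelled nZVI (980 higher, 1130 lower). Over the mean of the 3 conditions 3828 genes changed, 1858 higher and 1970 lower (1950 and 1858 with RLE), and 372 of them at least 2-fold. In all 3 conditions 143 genes were higher and 296 lower at 4 h, where independent lists would share 4.45 and 6.99. The labelled control count was 1275 without control 1 h replicate 2, 1274 without control 1 h replicate 3 and 966 without control 4 h replicate 1. The nFe3O4 count was 596 without nFe3O4 1 h replicate 3 and 987 without nFe3O4 4 h replicate 1, and in a fit on the 2 groups alone it was 578 for nFe3O4 and 1372 for labelled nZVI. With the covariate added after seeing the data, 3240 genes changed in the labelled control and 2470 with nFe3O4. Lane 1 alone gave 1087 in the labelled control, 781 with nFe3O4, 1149 in labelled nZVI and 2464 over the mean. The direction of the larger number turned with the scaling in the labelled control and over the mean, so no majority direction is read from these counts. Between conditions, 84 genes changed in opposite directions over time in the labelled control and labelled nZVI, 7 in the labelled control and nFe3O4, and 11 in nFe3O4 and labelled nZVI, and r across genes was 0.295, 0.485 and 0.591. The authors' deposited table of 4 h against 1 h listed 5408 genes.

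**Figure D4:**
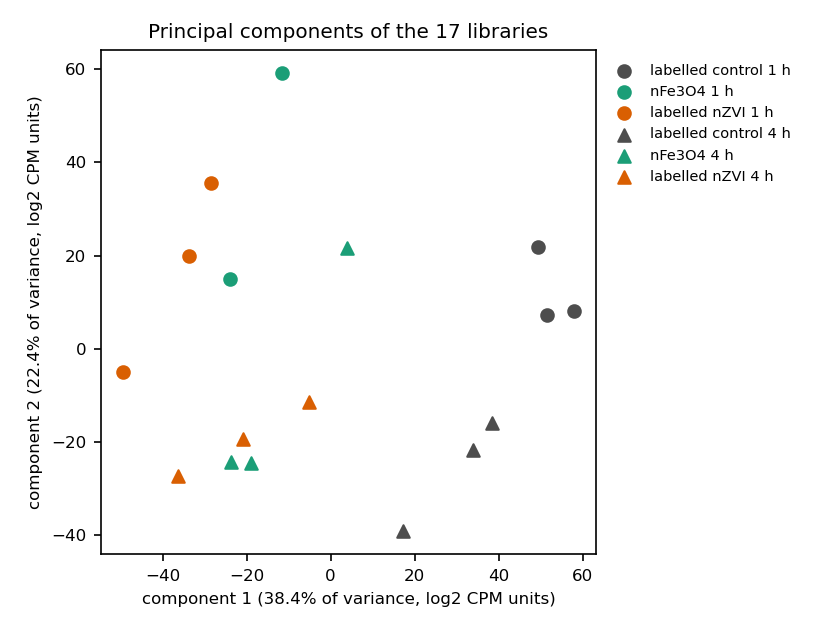
Scores of the 17 libraries on the first (38.4% of variance, horizontal axis) and the second (22.4%, vertical axis) principal component of log2 CPM, coloured by group, with circles for 1 h and triangles for 4 h. The labelled control libraries lie at 17.2 to 57.9 on the first component and the labelled nZVI libraries at -49.4 to -5.21, while nFe3O4 replicate 3 lies above the other nFe3O4 libraries of its hour on the second, at 59.1 for 1 h and 21.6 for 4 h.

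On the principal components the labelled control libraries of both hours lay at one side of the first component, from 17.2 to 57.9, and the labelled nZVI libraries at the other, from -49.4 to -5.21. The nFe3O4 libraries lay between -23.9 and 3.84. Replicate 3 of nFe3O4 stood apart on the second component, at 59.1 against 14.9 for replicate 1 at 1 h, and at 21.6 against -24.2 and -24.4 for replicates 1 and 2 at 4 h. Of the 49 genes that the authors listed for their high variance over these samples, 46 changed with nFe3O4 at 1 h, 48 in labelled nZVI at 1 h, 34 with nFe3O4 at 4 h and 33 in labelled nZVI at 4 h against the labelled control. Between labelled nZVI and nFe3O4 at 1 h, 3 of them changed. The list was chosen on these samples and is not independent evidence of any of these changes.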

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

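The tests of the names, the heading order and the reversed sign were chosen only after the mismatch had been seen; the other tests in this part were set before their results.

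Effects of the particles that differed between the hours were singled out because the difference itself passed a test. The effect of labelled nZVI at 4 h minus that at 1 h passed edgeR's test in 1098 genes, and on the log2 scale the difference was 3.10 for RSUB_11916, 2.90 for RSUB_07490, -2.33 for RSUB_09199 and -2.23 for RSUB_12662. The effect of nFe3O4 differed in 233 genes (46 with the names control and nZVI exchanged), with 3.54 for RSUB_07490, 3.01 for RSUB_11916, -1.87 for RSUB_11161 and -1.81 for RSUB_11583. The 233 fell to 18 and the 4 nFe3O4 genes no longer passed without nFe3O4 1 h replicate 3, with adjusted p between 0.0774 and 0.118 in edgeR's fit and differences of 2.99, 2.46, -1.68 and -1.65. The 233 were 143 without control 1 h replicate 1, 100 without control 1 h replicate 3, 125 without nFe3O4 4 h replicate 3 and 78 without control 4 h replicate 1. RSUB_11161 also failed without any of the 3 control libraries just named, with adjusted p of 0.0519, 0.058 and 0.0566. The 1098 were 633 without control 1 h replicate 3, 532 without control 4 h replicate 1, 652 without nZVI 4 h replicate 1 and 638 without nZVI 4 h replicate 2. Of 50 drawn splits of the libraries by hour within condition, 1 gave as many genes as the 1098, the real one, and the highest other gave 975, more than without any of the 4 libraries just named. Splits that exchange hours put the hour effect into the spread within groups, so they do not test whether a difference of effects of this size arises without one.

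The names control and nZVI stand for different libraries in the count table and in the authors' transformed and comparison tables. A reversed sign in the authors' comparisons is argued against, because their nFe3O4 against control fold changes at 1 h correlated across genes at -0.041 with the same comparison here, where a reversed sign needs a value below -0.8. Exchanged names in one of the tables remain open and fit the values: 12 of 12 libraries matched the other name. The authors' nFe3O4 against control fold changes correlated across genes with labelled nZVI against nFe3O4 here, at -0.966 at 1 h and -0.992 at 4 h. Their nZVI against nFe3O4 fold changes correlated with nFe3O4 against the labelled control here, at -0.973 at 1 h and -0.984 at 4 h. A heading row sorted another way was not tested by the column order: the 17 of 17 distinct libraries that matched the library at the same place follow from the exchanged names and the order of the headings. These tables do not tell which headings are right, so it stays open whether the labelled control or the labelled nZVI libraries came from particle-free cultures, and with it whether nFe3O4 differs from particle-free algae in 3424 genes at 1 h and 2720 at 4 h or in 365 and 1. The headings of the authors' transformed table pair each name with a running sample number, which those of the count table lack. The count table also holds the copied columns. Both points count against the headings of the count table without settling the question, since such numbers move with the names.

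The authors' comparison tables list more genes than library sums gave here, 5645 against 2353 for nZVI against control at 4 h. Lane sums entered as samples are argued against, since the authors' standard errors were 0.485 times those of DESeq2 on lane sums (median over 1988 genes). Lanes entered as separate samples remain open and fit the values, since the ratio to DESeq2 on lane columns was 0.997, and lane columns as samples gave 5668 genes by edgeR. The authors' transformed table also holds a separate column for each lane. Lanes of a library repeat the same culture, so such counts may overstate what independent cultures would give. No biological explanation was tested for this difference.

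Libraries of the same group differed along a shared axis that held 40.4% of the variance within groups, against 9.09% if it were even over the residual degrees of freedom. Depth is argued against: after thinning each library to the depth of the shallowest the axis held 39.8%. A few genes taking most of the counts is argued against too, since 57.5% of genes had a loading of the same sign under total-count scaling, where that cause needs at least 90%; it replaced an earlier test, void because removing the 25 most abundant genes changes little where TMM already trims them (40.4%). A difference between cultures in growth or handling may stay behind it and was not tested, as the labels give no batch. With the axis as a covariate, chosen after seeing the data, 341 genes passed between labelled nZVI and nFe3O4 at 4 h, against 1 without.

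Splits of 6 libraries into groups of 3 number 10, too few for a share under 0.05. In each case below, 1 split gave as many genes, the real one, and the highest other gave 0, where mixing unlike libraries in a group also raises the spread that each difference is tested against. The real values were 4892 for labelled nZVI against labelled control at 1 h, 2353 for the same at 4 h, 2720 for nFe3O4 against labelled control at 4 h, 1 for labelled nZVI against nFe3O4 at 4 h, 2028 for the hours in the labelled control and 2110 for the hours in labelled nZVI. For the hours over the mean of the 3 conditions, 1 of 50 drawn splits gave as many genes as the real 3828, and the highest other gave 2718. That share is under 0.05 if libraries can be exchanged freely between the hours of a condition. The protocol says flasks were sampled at both hours, so they may not be, and chance assignment of hours is not called excluded.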

How the results depend on the processing

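Alternatives were planned before the data were examined, except 3 chosen after seeing them: the exchanged names, the copied columns as a library and the shared axis as a covariate. Besides fits that leave out 1 library, the alternatives gave 141 counts of changed genes, of which 82 were within 1.5 times the reported count, 56 moved further and 3 reversed. Of the 105 planned ones 64 were within 1.5 times, including every count with RLE size factors, with no low-count filter and with the stricter filter. With RLE the larger number of genes turned direction in all 4 comparisons with the labelled control (1691 higher and 1719 lower, 2364 and 2509, 1284 and 1433, 1147 and 1221), in the labelled control over time (1042 and 919) and over the mean (1950 and 1858). Exchanged names apart, the alternatives gave 784 fold changes of named genes. Of these 759 had the reported sign and passed the threshold, 25 had the reported sign without passing it and 0 had the other sign. Counts of changed genes are given below for labelled groups, and the cause of a move was not tested unless stated. Tests of gene lists with an estimated correlation, with fry or with RLE factors were not run, since the files hold no gene names. The 3 controls per hour were not split.

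With DESeq2 the counts were 663 for labelled nZVI against nFe3O4 at 1 h, 26 for the same at 4 h, and 460 for the difference of nFe3O4 effects. Fits on only the 2 groups compared, which hold fewer libraries, gave 2 genes for labelled nZVI against nFe3O4 at 1 h, 578 for 4 h against 1 h with nFe3O4 and 1372 in labelled nZVI. A fold change of at least 2 lowered the counts by construction. Against the labelled control they were 1166 (nFe3O4, 1 h), 1804 (labelled nZVI, 1 h), 512 (nFe3O4, 4 h) and 485 (labelled nZVI, 4 h), and between the particles at 1 h 56. For 4 h against 1 h they were 464 in the labelled control, 441 with nFe3O4, 471 in labelled nZVI and 372 over the mean, and for the differences of effects 439 (labelled nZVI) and 127 (nFe3O4).

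The protocol says flasks were sampled at both hours, so libraries of the 2 hours may come from the same flasks. The labels do not say that a number marks the same culture at both hours, and same-numbered libraries were not shown to be paired. Between the hours of a condition, r of their deviations from the group means was 0.478 and 0.654 with nFe3O4, 0.302, -0.0238 and 0.46 in labelled nZVI and 0.104, 0.0421 and -0.00877 in the labelled control. A library's highest r was with its own number in 7 of 12 cases between hours, a hint from the data, and in 5 of 24 between conditions, where r ran from -0.503 to 0.399. These tallies leave out every pair of groups with nFe3O4 1 h, which has 2 libraries, and so the r of 0.478, 0.654 and -0.503. With the culture (condition and number) as a replicate block, 3168 genes changed in the labelled control over time, 1995 in the difference of labelled nZVI effects and 695 in that of nFe3O4 effects; the cause was not tested. The replicate block by number moved no count by over 1.5 times, and no named gene lost its call under either block.

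Lane columns entered as separate samples are not independent, which raised the counts. They were 5964 and 5749 for nFe3O4 against the labelled control at 1 h and 4 h, 5668 for labelled nZVI against it at 4 h, and 3727 and 1519 between the particles at 1 h and 4 h. For 4 h against 1 h they were 5233 in the labelled control, 4660 with nFe3O4, 5067 in labelled nZVI and 6688 over the mean, and for the differences of effects 4234 (labelled nZVI) and 2781 (nFe3O4). Lane 1 alone shows what depth limits. It gave 2202 and 1466 genes for nFe3O4 against the labelled control at 1 h and 4 h, 1226 for labelled nZVI at 4 h and 87 between the particles at 1 h. For 4 h against 1 h it gave 1087 in the labelled control, 781 with nFe3O4, 1149 in labelled nZVI and 2464 over the mean, and for the differences of effects 387 (labelled nZVI) and 114 (nFe3O4).

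Leaving out 1 library at a time moved 24 of 91 counts by over 1.5 times. The ranges were 2123 to 3056 for nFe3O4 against the labelled control at 1 h (2123 without nFe3O4 1 h replicate 3) and 1704 to 2923 at 4 h (1704 without nFe3O4 4 h replicate 1, 1754 without control 4 h replicate 3, 1806 without nFe3O4 4 h replicate 3). For labelled nZVI against the labelled control they were 4004 to 4711 at 1 h and 1369 to 2273 at 4 h (1369 without nZVI 4 h replicate 3). Between the particles they were 12 to 353 at 1 h (12 without nFe3O4 1 h replicate 3, 131 without nZVI 1 h replicate 3, 158 without nFe3O4 1 h replicate 1, 185 without nZVI 1 h replicate 2) and 1 to 4 at 4 h (4 without nZVI 4 h replicate 3). For 4 h against 1 h they were 966 to 1681 in the labelled control (966 without control 4 h replicate 1, 1274 without control 1 h replicate 3, 1275 without control 1 h replicate 2), 596 to 1380 with nFe3O4 (596 without nFe3O4 1 h replicate 3, 987 without nFe3O4 4 h replicate 1), 1433 to 1898 in labelled nZVI and 3094 to 4126 over the mean. The difference of labelled nZVI effects ran from 532 to 1257 (532 without control 4 h replicate 1, 633 without control 1 h replicate 3, 638 without nZVI 4 h replicate 2, 652 without nZVI 4 h replicate 1). That of nFe3O4 effects ran from 18 to 231 (18 without nFe3O4 1 h replicate 3, 78 without control 4 h replicate 1, 100 without control 1 h replicate 3, 125 without nFe3O4 4 h replicate 3, 143 without control 1 h replicate 1). Where nFe3O4 1 h was left with 1 library, that library was assumed to vary like those of the other groups.

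Exchanging the names control and nZVI reverses directions by construction. The count against the control for nZVI stayed at 4892 at 1 h and 2353 at 4 h, and the difference of its effects at 1098, with higher and lower swapped. For nFe3O4 against control the counts became 365 at 1 h and 1 at 4 h, for nZVI against nFe3O4 3424 and 2720, and for the difference of nFe3O4 effects 46. The log2 fold changes for nFe3O4 against control became -0.15 for RSUB_09261 and -0.44 for RSUB_08785 at 1 h and -0.13 for RSUB_07060 at 4 h, with adjusted p in edgeR of 0.836, 0.329 and 0.948. Those for nZVI against control became -4.32 for RSUB_08785, -4.28 for RSUB_07060, 3.79 for RSUB_11916 and 3.14 for RSUB_08235 at 1 h, and -3.42 for RSUB_07060, -3.25 for RSUB_12703, 1.96 for RSUB_12574 and 1.77 for RSUB_02480 at 4 h. For nZVI against nFe3O4 they became 1.40 for RSUB_08164 and 0.59 for RSUB_12574 at 1 h and 0.45 for RSUB_12574 at 4 h. The difference of nZVI effects became -3.10 for RSUB_11916, -2.90 for RSUB_07490, 2.33 for RSUB_09199 and 2.23 for RSUB_12662, and that of nFe3O4 effects -0.089 for RSUB_11916, 0.081 for RSUB_11161 and 0.40 for RSUB_11583, with adjusted p in edgeR of 0.982, 0.976 and 0.726. The other 15 of these 21 still passed. Of 24 with the reported sign 16 passed and 8 did not: nFe3O4 against control, RSUB_07490 and RSUB_08235 at 1 h (edgeR adjusted p 0.512 and 0.676) and RSUB_09261, RSUB_02480 and RSUB_04006 at 4 h (0.998, 0.911 and 0.811), time in nZVI, RSUB_07490 and RSUB_11916 (0.143 and 0.361), and the difference of nFe3O4 effects, RSUB_07490 (0.793).

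With the copied columns kept as a further library the counts were 946 and 3 for labelled nZVI against nFe3O4 at 1 h and 4 h and 415 for the difference of nFe3O4 effects, since a copy lowers the apparent spread. With the shared axis as a covariate they were 1675 (956 higher, 719 lower) and 341 (280 higher, 61 lower) between the particles at 1 h and 4 h, 3670 for labelled nZVI against the labelled control at 4 h, 3240 over time in the labelled control and 2470 with nFe3O4, and 2035 and 641 for the differences of labelled nZVI and nFe3O4 effects. That covariate was estimated from the same libraries, so its counts are not independent evidence, and the cause was not tested.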

Other observations

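The tests in this part were all chosen after seeing the data. Among the 10 genes with the highest mean CPM, RSUB_08944 stood at 36360 CPM ± 991 (SD, n = 3) in the labelled control at 1 h, 25330 CPM ± 2600 (SD, n = 2) with nFe3O4 and 23670 CPM ± 2120 (SD, n = 3) in labelled nZVI. At 4 h it stood at 50610 CPM ± 2210, 43240 CPM ± 4220 and 41150 CPM ± 3000 (SD, n = 3 each). RSUB_00393 stood at 13340 CPM ± 129 (SD, n = 3), 9058 CPM ± 960 (SD, n = 2) and 7912 CPM ± 1120 (SD, n = 3) at 1 h, in the same order. By edgeR's test with Benjamini-Hochberg adjustment, RSUB_00393 differed from the labelled control at 1 h by -0.56 on the log2 scale with nFe3O4 (adjusted p = 0.0017) and by -0.75 in labelled nZVI (adjusted p = 2.67e-05). Of the 10 genes, 5 did not pass against the labelled control at either hour, with adjusted p between 0.107 and 0.96, and RSUB_08944 and RSUB_08942 did not pass with nFe3O4 at 4 h (adjusted p = 0.0619 and 0.0659). Over the mean of the 3 conditions RSUB_00393 rose by 0.77 between 1 h and 4 h (adjusted p = 2.13e-07). RSUB_08944 has a neighbour, RSUB_08942, with near-equal values (35380 CPM ± 890 in the labelled control at 1 h, SD, n = 3), so whether their reads can be told apart is uncertain.

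Fold changes of loci with consecutive numbers were correlated across 10828 pairs, with r = 0.102 for nFe3O4 and 0.102 for labelled nZVI against the labelled control at 1 h, and 0.0844 and 0.0847 at 4 h. At a distance of 2 numbers r was between 0.00659 and 0.0155 over 10747 pairs. Pairs of genes are not independent replicates, and locus numbers were taken as the files give them, with no genome used here.

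The authors' transformed table holds values of its own for nFe3O4 1 h replicate 2. The copied columns of the count table correlated with that library at 0.926 across genes and with replicate 1 at 0.978. The count table therefore lacks a library that the transformed table has.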
